A study of Mus musculus with 15 samples.

How the data were processed

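Tumour blocks of the mouse MC38 syngeneic model were profiled by strand-specific mRNA sequencing, with 5 tumours each from mice given vehicle, anti-PD-1, or BG136 plus anti-PD-1. The series title and the design description name different source organisms for BG136, so none is given here. Replicate numbers in the titles name tumours and do not pair them across groups.

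The deposited table holds 1 column per library, and its header calls the values only expression. Its values were read as FPKM (fragments per kilobase of transcript, scaled to the library's mapped fragments) computed by the authors. This unit was inferred from the values and from the presence of Cufflinks among the tools in the submitters' notes. For the authors' processing those notes also name Trimmomatic, HISAT2, HTSeq and DESeq, without versions or roles, and state the genome build GRCm39. The annotation used here for gene lengths and synonyms is of an earlier build, so no coordinates are printed. No scaling between libraries beyond FPKM was seen. The table has 21878 entries. Of these 27 whose symbols had been turned into dates by spreadsheet software were left out, which removed at most 0.168% of a library's FPKM sum. The file holds no columns of a comparison by the authors, so the planned overlap with such a comparison was not run.

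Genes with at least 1 FPKM in at least 5 libraries were tested, 11311 in all. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3: lmFit over all 15 libraries with 3 group means, then eBayes with a trend. The tests were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. The 3 comparisons were BG136 plus anti-PD-1 against vehicle, anti-PD-1 against vehicle, and BG136 plus anti-PD-1 against anti-PD-1. Log2 changes are given ± SE and FPKM means ± SD. The tumours are taken as independent, which was not tested. The library names carry prefixes that differ between vehicle replicate 1 and the other vehicle libraries, and between combination replicate 1, replicates 2 and 3, and replicates 4 and 5. The sources used here do not say whether these name cohorts, and they were not used as batches.

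The 37 gene lists (487 members, 15 matched by synonym and 19 not matched) were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Of these lists 34 had at least 3 tested members. B and plasma cell, skin keratinocyte and mitochondrially encoded genes were not tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes. Beside it stand camera with an estimated correlation, under which no list passed in any comparison (0, 0 and 0, against 23, 17 and 21), and fry, which asks whether a list's genes move one way on balance (21, 0 and 0 lists). An exact permutation test of each library's mean over a list was added after the data were seen. Named genes were, per comparison, the 7 largest rises and the 7 largest falls among genes past the threshold with at least 5 FPKM in the higher group, without predicted genes, pseudogenes and receptor segments. The 2 members with the smallest p from each of at most 10 lists were added, and 8 genes were always named (Pdcd1, Cd274, Clec7a, Cd8a, Gzmb, Ifng, Adgre1 and Ly6g). Where fewer than 10 genes passed, the 10 with the smallest p were taken. Oas2 and Ifit1 are also given for the combination, where the rule did not name them, and so are Cma1 and Mcpt4.

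No read counts were used here, so the depth of each library is unknown and intervals that need it are not given. The depth of a library relative to vehicle replicate 1 was read from the smallest step of genes with a mean of at most 0.3 FPKM, over 54 to 89 genes per compared library. In 13 of the 14 compared libraries at least 86.4% of these genes were within 3% of 1 factor, and in combination replicate 4 only 27.8% were. On simulated values the method erred by at most 0.0210%. Gene length was known for 10976 tested genes (97.0%). FPKM of genes with near-identical copies is uncertain: Gapdh is listed at 1.95 to 3.48 FPKM, beside 1237 to 1920 for Actb, and Gbp2b and the haemoglobin genes have close paralogs too.

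The fit was tested on simulated data built from the group spreads seen here, with genes drawn independently. Changes were put only in genes with a mean log2(FPKM + 1) of at least 2. At a 1.5-fold change it recovered 61, 52 and 57 of 67 changed genes in the comparisons in the order above, at 2-fold 65, 64 and 64 of 67, and at 4-fold all 66. It wrongly called 46, 8 and 63 unchanged genes, which is 19.3%, 4.21% and 25.2% of its calls, so the 5% of the threshold was exceeded in both comparisons with the combination group. The wrong calls were more numerous in the comparisons with the combination group, whose median SD of log2 values was 0.164 against 0.0913 for vehicle and 0.0960 for anti-PD-1. Fits with weights per group and with the compared groups alone were therefore added after the data were seen. Another 200 simulations without any changed gene, also added after the data were seen, drew genes independently or kept each library's residuals together with a random sign. Some gene was called in 76%, 4.5% and 81% of the former and in 10.5%, 1.5% and 11.5% of the latter. For lists, 1 list shifted 2-fold was called and 0 others in each comparison, with genes simulated as independent.

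Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, median-ratio and quantile scaling, no variance trend, weights per library, a replicate block, the skeletal muscle score as a covariate, an unadjusted p under 0.05 with a fold of at least 2, and leaving out each replicate in turn. Added later were the adipocyte covariate and the fit without combination replicates 3 and 5. Other splits of the 10 libraries of a comparison were counted over 100 of the 126 possible. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 served for depth, length trends and figures. A few single-gene results are not reported here, although the genes stayed in their lists and in the tests.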

Results

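Gene expression was measured by bulk mRNA sequencing in tumour blocks of the MC38 syngeneic model, in which a mouse colon adenocarcinoma line grows in mice of its own strain. Mice had received vehicle, an antibody against the checkpoint receptor PD-1, or BG136 plus anti-PD-1. BG136 is a purified soluble β-glucan, a polysaccharide class that innate immune cells sense through receptors such as Dectin-1 (Clec7a). Each of the 3 groups held 5 tumours, and 1 library was made per tumour, so 15 libraries were compared. The table listed 21851 genes by symbol in FPKM, of which 11311 were tested. The sum of FPKM per library lay between 377509 and 424899. The files give no read totals, so the absolute depth is unknown and no counting interval can be given. Depth relative to vehicle replicate 1, read from the spacing of the lowest values, lay between 0.832 and 1.07 in the 13 other libraries with a clear spacing.

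**Figure D1:**
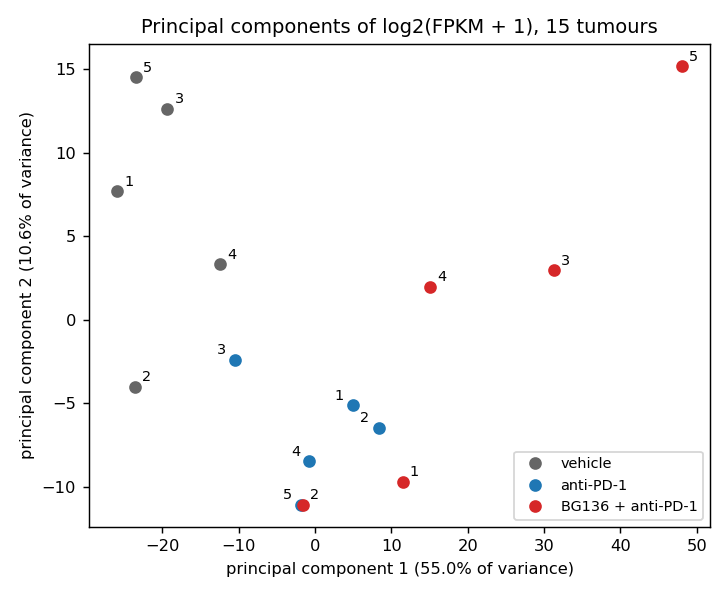
Principal components of log2(FPKM + 1) over the tested genes, with 1 point per library labelled by its replicate number and coloured by group. The horizontal axis holds 55.0% and the vertical axis 10.6% of the variance. The vehicle libraries lie at the left, and BG136 plus anti-PD-1 replicates 3 and 5 lie furthest right, at 31.3 and 48.1.

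BG136 plus anti-PD-1 against vehicle asks how the combined treatment changed the tumour block. Immune genes rose in the combination group. Pdcd1, which encodes PD-1, was at 13.6 ± 6.12 FPKM (SD, n = 5) against 3.52 ± 1.03 with vehicle, and Cd8a, the co-receptor of cytotoxic T cells, was at 16.7 ± 8.90 against 4.90 ± 0.853. The chemokine Ccl3 rose from 5.33 ± 1.03 to 28.3 ± 8.82 FPKM, a log2 change of 2.17 ± 0.20 (SE, limma adjusted p = 2.07e-05). Tgfb3, a ligand of the TGF-beta family, was at 17.0 ± 3.60 FPKM against 88.3 ± 26.6, a log2 change of -2.28 ± 0.22 (adjusted p = 2.15e-05). All 5 combination libraries lay above the vehicle mean for Pdcd1, Cd8a and Ccl3 and below it for Tgfb3.

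The largest rises among genes of at least 5 FPKM also took in Saa3, an acute-phase protein, at a log2 change of 2.68 ± 0.58, and Mmp3, the matrix protease stromelysin-1, at 2.55 ± 0.50. Gbp2b, an interferon-inducible GTPase, changed by 2.37 ± 0.40 and Clec4d, a C-type lectin receptor of myeloid cells, by 2.29 ± 0.34. Nppb, the precursor of brain natriuretic peptide, changed by 2.23 ± 0.36 and Cpxm1 by 2.18 ± 0.43. The largest falls were those of Tgfb3, of the transcription factor Osr2 at -2.19 ± 0.19, of Ogn, a proteoglycan of the extracellular matrix, at -2.14 ± 0.17, and of Lrrc17 at -2.07 ± 0.18. Gas1, a membrane protein linked to growth arrest, followed at -2.0 ± 0.21. Mmp9, the protease gelatinase B, changed by -1.86 ± 0.21 and Haus7, a subunit of the augmin complex of the mitotic spindle, by -1.85 ± 0.23. The adjusted p of these genes lay between 8.14e-06 for Ogn and 0.00270 for Saa3. In all 5 combination libraries each of them lay on the same side of the vehicle mean, although single Saa3 values of the groups overlapped. Being picked by their change in these same libraries favours this.

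Of the 11 tested members of the immune checkpoint and exhaustion list, 10 rose and 0 fell (camera adjusted p = 1.80e-07, 10 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). Tigit, an inhibitory receptor of T and NK cells, changed by 1.44 ± 0.20 and Pdcd1 by 1.63 ± 0.23. In the beta-glucan recognition and signalling list 11 of 15 members rose and 0 fell (adjusted p = 2.70e-07, 11 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). Pycard, the inflammasome adaptor ASC, changed by 1.05 ± 0.15 and Fcer1g, the signalling chain of Fc and lectin receptors, by 1.15 ± 0.18. The receptor Clec7a itself did not pass, at 0.64 ± 0.30 (adjusted p = 0.0956). This list was also higher with anti-PD-1 alone, without BG136, by a mean of 0.287 (camera adjusted p = 9.68e-04, 0.590 with an estimated correlation). Its rise is therefore not read as a response to the glucan. In the cytotoxic lymphocyte list 9 of 12 rose and 0 fell (adjusted p = 2.70e-07, 11 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). Nkg7, a granule protein, changed by 1.74 ± 0.25, Cd8a by 1.48 ± 0.23 and the cytokine Ifng by 1.78 ± 0.28, while the protease granzyme B (Gzmb) did not pass at 0.92 ± 0.42 (adjusted p = 0.0894). All 11 tested T cell members rose (adjusted p = 4.90e-07, 11 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). The CD3 chains Cd3g and Cd3d changed by 1.80 ± 0.25 and 1.27 ± 0.25.

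In the MHC class II presentation list 9 of 10 members rose and 0 fell (adjusted p = 7.49e-07, 9 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). H2-Ab1 changed by 1.79 ± 0.27 and Ciita, the master regulator of these genes, by 1.43 ± 0.23. Of 13 macrophage and monocyte markers 10 rose and 0 fell (adjusted p = 1.60e-06, 10 adjusted over the list alone, adjusted p = 0.306 with an estimated correlation). The complement component C1qb changed by 1.02 ± 0.17 and the macrophage surface antigen Adgre1 by 0.92 ± 0.23. In the complement list 10 of 12 rose and 0 fell (adjusted p = 1.61e-05, 10 adjusted over the list alone, adjusted p = 0.306 with an estimated correlation). Serping1 changed by 1.86 ± 0.33 and C4b by 1.37 ± 0.30. In the chemokine list 11 of 16 rose and 2 fell (adjusted p = 1.11e-04, 11 and 2 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). Ccl4 changed by 1.78 ± 0.17. The members that fell, named after their values were seen, were the monocyte attractant Ccl2 at -0.41 ± 0.14 and Xcl1, which attracts cross-presenting dendritic cells, at -1.22 ± 0.32.

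The interferon lists moved in opposite directions. Of 18 interferon gamma response genes 11 rose and 0 fell (adjusted p = 5.69e-05, 12 adjusted over the list alone, adjusted p = 0.409 with an estimated correlation). Cd274, the PD-1 ligand PD-L1, changed by 1.13 ± 0.20 and Irf8 by 0.93 ± 0.22. Of 16 type I interferon response genes 0 rose and 11 fell (adjusted p = 2.57e-04, 12 adjusted over the list alone, adjusted p = 0.437 with an estimated correlation). Ifit1, an antiviral RNA-binding protein, changed by -0.94 ± 0.13 and the oligoadenylate synthetase Oas2 by -0.82 ± 0.18. Endothelial markers rose in 8 of 12 cases and fell in 0 (adjusted p = 5.77e-05, 9 adjusted over the list alone, adjusted p = 0.346 with an estimated correlation). Pecam1 (CD31) changed by 1.02 ± 0.22 and Egfl7 by 0.73 ± 0.17. All 4 tested mast cell and eosinophil markers rose (adjusted p = 7.26e-04, 4 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). They are mast cell proteases. Cma1 changed by 1.91 ± 0.33 and Mcpt4 by 1.90 ± 0.35. The neutrophil marker Ly6g was not tested, being listed at 0 in 14 libraries.

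Adipocyte markers were also higher as a list in the combination group, by a mean log2 of 1.38, although 0 of 9 members passed (adjusted p = 0.00792, 0 adjusted over the list alone, adjusted p = 0.445 with an estimated correlation). Skeletal muscle markers were higher by a mean of 1.12 with 0 of 13 members past (adjusted p = 0.0158, 0 adjusted over the list alone, adjusted p = 0.558 with an estimated correlation). Red blood cell genes rose in 2 of 4 cases (adjusted p = 0.0250, 3 adjusted over the list alone, adjusted p = 0.408 with an estimated correlation). Epithelial tumour cell markers rose in 1 of 6 (adjusted p = 0.0244, 5 adjusted over the list alone, adjusted p = 0.445 with an estimated correlation). Their calls rested on single libraries except for adipocyte. The skeletal muscle mean was 1.75 without combination replicate 4, and its call ended without combination replicate 2 (adjusted p = 0.0531), vehicle replicate 3 (0.766, adjusted p = 0.0561) or vehicle replicate 5 (0.751, adjusted p = 0.0607). The red blood cell call ended without combination replicate 4 or 5 (adjusted p = 0.0560 and 0.0603), and the epithelial one without combination replicate 3, 4 or 5 (adjusted p = 0.0958, 0.135 and 0.176). By the exact permutation test of list scores 0 of these 4 passed, with p = 0.254 for skeletal muscle, 0.127 for adipocyte, 0.0635 for red blood cell and 0.0476 (adjusted p = 0.0736) for epithelial tumour cell. The epithelial markers lay near the floor, with a mean log2(FPKM + 1) of 0.371 with vehicle and 1.18 with the combination. Whether they come from the MC38 cells or from other cells of the block was not tested, so their rise is not read as one of tumour cells.

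Further lists were higher with the combination. In the pro-inflammatory macrophage list 6 of 8 members rose (adjusted p = 1.37e-04, 6 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). Alternatively activated macrophage genes rose in 3 of 10 cases (adjusted p = 0.00689, 3 adjusted over the list alone, adjusted p = 0.346 with an estimated correlation). In the matrix metalloproteinase and invasion list 5 of 10 rose and 1 fell (adjusted p = 0.0156, 6 and 2 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). For MHC class I presentation 5 of 14 rose and 1 fell (adjusted p = 0.0174, 5 and 1 adjusted over the list alone, adjusted p = 0.445 with an estimated correlation). In the immediate early and heat shock list 5 of 12 rose and 1 fell (adjusted p = 0.0244, 6 and 2 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). Regulatory T cell markers rose in 3 of 4 cases (adjusted p = 0.0303, 3 adjusted over the list alone, adjusted p = 0.306 with an estimated correlation). NK cell markers rose in 2 of 5 (adjusted p = 0.0331, 2 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). Calls ended without combination replicate 2 for immediate early and heat shock (adjusted p = 0.0531), replicate 3 for NK cell (0.0512), replicate 4 for MHC class I (0.0684) and replicate 5 for regulatory T cell (0.0635). Under some other setting of camera at the preset correlation, the call of every list in this paragraph except pro-inflammatory macrophage ended, alternatively activated macrophage and matrix metalloproteinase included.

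The other 11 lists did not pass camera: neutrophil (adjusted p = 0.208), apoptosis and p53 targets (0.238), ribosomal protein (0.283), dendritic cell (0.314), replication-dependent histone (0.538), fibroblast and matrix (0.552), unfolded protein response (0.652), proliferation (0.652), hypoxia and glycolysis (0.749), oxidative phosphorylation (0.805), and epithelial-mesenchymal transition and TGF-beta targets (0.836). In the last of these 4 of 15 members rose and 5 fell. By fry the epithelial-mesenchymal transition and unfolded protein response lists did pass (fry adjusted p = 0.00349 and 0.0320). Skeletal muscle (0.234), adipocyte (0.0993), epithelial tumour cell (0.0913) and MHC class I (0.0794), which passed camera, did not pass fry. For the histone list the median was -0.02 and the mean 0.04. An exact permutation test of each library's mean over a list, two-sided and added after the data were seen, passed 19 lists, 18 of them also past camera (smallest possible p 0.00794). MHC class I presentation was not among the 19 (exact adjusted p = 0.0642).

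Across all genes 4578 of 11311 passed, 1872 higher and 2706 lower with the combination, and the median log2 size of these changes was 0.36. At least 2-fold changes numbered 390, of which 339 were higher. Of 37 named genes tested, 35 passed, and all 35 kept their call under each alternative run for named genes. Those alternatives were both pseudocounts, median-ratio and quantile scaling, the replicate block, and the fits without single libraries or without combination replicates 3 and 5. Covariates, weights, the compared groups alone and the 2-fold rule were not run for named genes. Most of these genes were named for a large change or small p in the same data, which favours stable calls. Without combination replicates 3 and 5 the count was 3179. With the adipocyte score as a covariate it was 2519, with the rule of an unadjusted p and a 2-fold change it was 413. Under median-ratio scaling 55.7% of 4081 genes were higher in place of 40.9%.

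**Figure D2:**
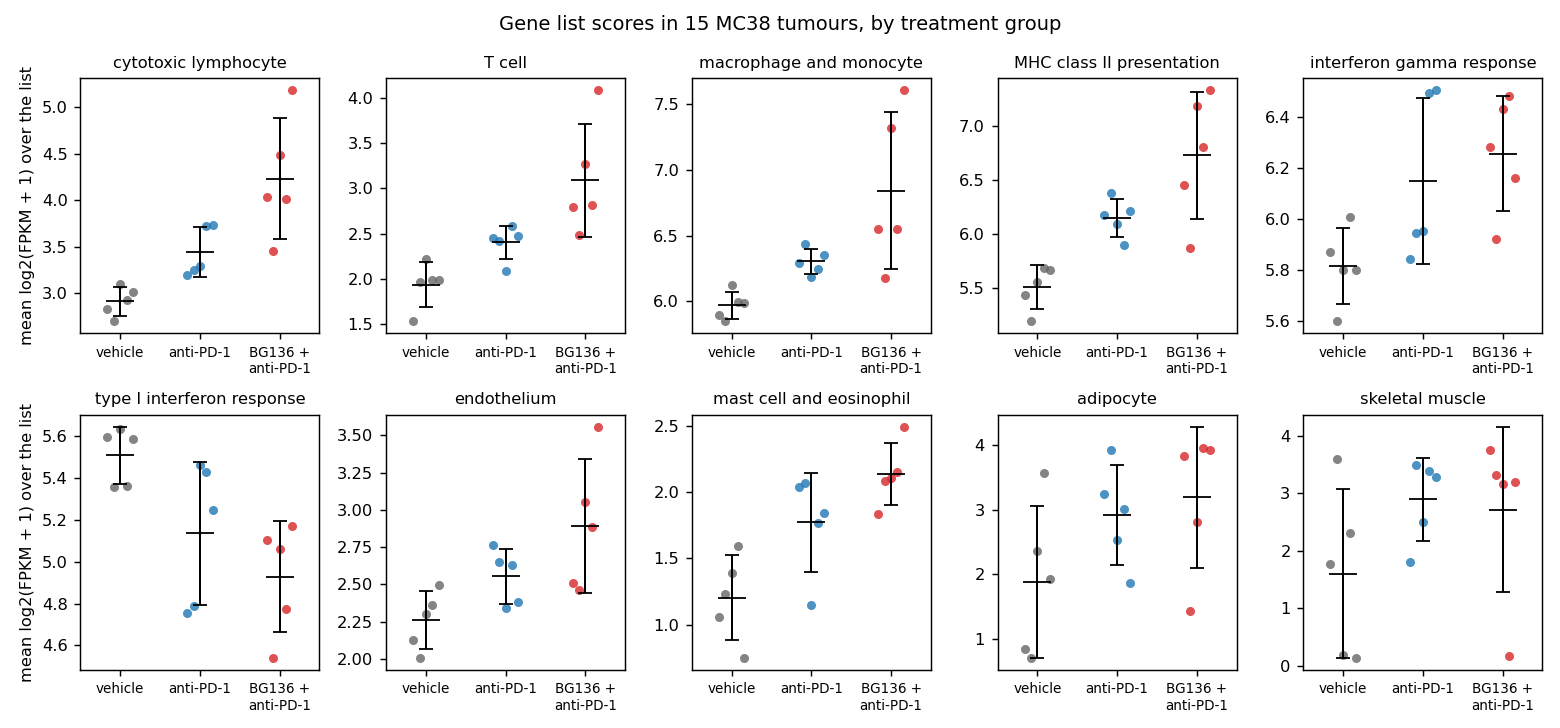
Mean log2(FPKM + 1) over the members of 10 gene lists that the table holds, with 1 point per library, 5 libraries per group, and the group mean ± SD. The cytotoxic lymphocyte, T cell and MHC class II scores lie above the vehicle mean in all 5 combination libraries, the type I interferon score lies below it in all 5, and the skeletal muscle score of combination replicate 4 is at 0.173.

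Anti-PD-1 against vehicle asks what the antibody alone changed. The same chemokine Ccl3 rose from 5.33 ± 1.03 to 15.3 ± 2.54 FPKM (SD, n = 5), a log2 change of 1.37 ± 0.20 (SE, limma adjusted p = 0.00346). Ifng rose from 2.53 ± 0.120 to 7.67 ± 3.59, a change of 1.20 ± 0.28 (adjusted p = 0.0224). Ogn fell from 55.6 ± 3.57 to 16.2 ± 3.85 FPKM, a change of -1.74 ± 0.17 (adjusted p = 3.17e-04), and Tgfb3 fell from 88.3 ± 26.6 to 33.4 ± 11.6, a change of -1.38 ± 0.22 (adjusted p = 0.00465). All 5 anti-PD-1 libraries lay on the same side of the vehicle mean for each of these genes.

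The largest rises were those of Gbp2b at 1.73 ± 0.40, Pi16 at 1.65 ± 0.34, the serine protease inhibitor Serpina3n at 1.62 ± 0.44 and Clec3b (tetranectin) at 1.61 ± 0.42. Next came the lipopolysaccharide-binding protein Lbp at 1.5 ± 0.29, the secreted glutathione peroxidase Gpx3 at 1.49 ± 0.36, and Ccl3. The largest falls were those of Lrrc17 at -1.77 ± 0.18, Ogn, Tgfb3, Tex101 at -1.62 ± 0.28, and Gas1 at -1.47 ± 0.21. Enpp2 (autotaxin, which makes lysophosphatidic acid) changed by -1.42 ± 0.22, and Osr2 by -1.34 ± 0.19. In each of these the 5 treated libraries lay beyond the vehicle mean, which their selection by change in the same libraries favours. Their adjusted p lay between 3.17e-04 for Ogn and 0.0453 for Serpina3n.

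Of 16 type I interferon response genes 1 fell and 0 rose (camera adjusted p = 7.11e-05, 8 fell adjusted over the list alone, adjusted p = 0.590 with an estimated correlation). Ifit1 changed by -0.56 ± 0.13, and Oas2, at -0.61 ± 0.18, did not pass (adjusted p = 0.0598). Anti-PD-1 replicates 1 and 2 held most of this difference, which was a mean of -0.371 with them and -0.128 without them. In the checkpoint and exhaustion list 3 of 11 rose and 0 fell (adjusted p = 1.11e-04, 9 adjusted over the list alone, adjusted p = 0.590 with an estimated correlation). Entpd1, the ectonucleotidase CD39, changed by 0.79 ± 0.20 and Tox, a transcription factor of exhausted T cells, by 0.57 ± 0.15. Pdcd1, at 0.73 ± 0.23 (adjusted p = 0.0811), and Cd274, at 0.57 ± 0.20 (adjusted p = 0.101), did not pass. In the MHC class II list 5 of 10 rose and 0 fell (adjusted p = 1.68e-04, 8 adjusted over the list alone, adjusted p = 0.590 with an estimated correlation). H2-DMb1 changed by 0.79 ± 0.20 and H2-Ab1 by 1.03 ± 0.27. In the chemokine list 2 of 16 rose, Ccl3 and, at 1.06 ± 0.17, Ccl4 (adjusted p = 9.68e-04, 7 adjusted over the list alone, adjusted p = 0.590 with an estimated correlation). The interferon gamma list was higher by a mean of 0.33 with 0 of 18 past (adjusted p = 1.60e-04, 4 adjusted over the list alone, adjusted p = 0.590 with an estimated correlation). Replicates 4 and 5 held most of it, and without them the mean was 0.0976. Ido1 was at 1.08 ± 0.33 (adjusted p = 0.0676) and Iigp1 at 0.55 ± 0.17 (adjusted p = 0.0697).

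Among lymphocyte and myeloid lists, 2 of 12 cytotoxic lymphocyte members rose (adjusted p = 0.00206, 6 adjusted over the list alone, adjusted p = 0.590 with an estimated correlation). They were Ifng and Cd8a, the latter at 0.81 ± 0.23 (adjusted p = 0.0490), while Gzmb was at 0.09 ± 0.42 (adjusted p = 0.921). In the T cell list 1 of 11 rose, Cd3g at 0.94 ± 0.25, and Cd3e was at 0.71 ± 0.30 (adjusted p = 0.177). The T cell list's adjusted p was 0.00242, with 1 adjusted over the list alone and adjusted p = 0.590 with an estimated correlation. In the beta-glucan list 2 of 15 rose, Plcg2 at 0.37 ± 0.10 and Pycard at 0.55 ± 0.15 (adjusted p = 9.68e-04, 5 adjusted over the list alone, adjusted p = 0.590 with an estimated correlation). Clec7a was at -0.06 ± 0.30 (adjusted p = 0.923). In the complement list 1 of 12 rose, Serping1 at 1.23 ± 0.33, and C4b was at 0.92 ± 0.30 (adjusted p = 0.0851). The complement list's adjusted p was 0.00206, with 3 adjusted over the list alone and adjusted p = 0.590 with an estimated correlation. For mast cell and eosinophil markers 0 of 4 passed (adjusted p = 0.00206, 4 adjusted over the list alone, adjusted p = 0.590 with an estimated correlation). Mcpt4 was at 1.25 ± 0.35 (adjusted p = 0.0502) and Cma1 at 1.16 ± 0.33 (adjusted p = 0.0568). The macrophage and monocyte list was higher with 0 of 13 past (adjusted p = 0.00533, 0 adjusted over the list alone, adjusted p = 0.590 with an estimated correlation). Adgre1 was at 0.38 ± 0.23 (adjusted p = 0.341). The calls of the complement list and of the macrophage and monocyte list ended under some other setting of camera at the preset correlation.

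Admixed-tissue lists moved here too: skeletal muscle was higher by a mean of 1.29 (adjusted p = 0.00259) and adipocyte by 1.1 (adjusted p = 0.0122), with 0 members past in either, 0 adjusted over the list alone, and adjusted p = 0.590 with an estimated correlation for both. The other lists that passed were pro-inflammatory macrophage (1 of 8 rose, adjusted p = 0.00689, 3 adjusted over the list alone), endothelium (0 of 12, adjusted p = 0.0126, 0 adjusted over the list alone), proliferation (1 of 18 rose, adjusted p = 0.0179, 3 adjusted over the list alone) and MHC class I presentation (1 of 14 rose, adjusted p = 0.0201, 1 adjusted over the list alone). Each of these 4 had an adjusted p = 0.590 with an estimated correlation. Calls ended for adipocyte without vehicle replicate 1 or 2 or anti-PD-1 replicate 2 (adjusted p = 0.0506, 0.0653 and 0.0595) and for endothelium without anti-PD-1 replicate 1 (0.0731). The same held for proliferation without vehicle replicate 1 or anti-PD-1 replicate 5 (0.0543 and 0.0550) and for MHC class I without vehicle replicate 2 or anti-PD-1 replicate 4 or 5 (0.0624, 0.0778 and 0.0816). The 17 lists that did not pass ranged in adjusted p from 0.0571 for matrix metalloproteinase and invasion to 0.925 for neutrophil. Between them lay hypoxia and glycolysis (0.101), alternatively activated macrophage (0.101), oxidative phosphorylation (0.149), ribosomal protein (0.211), red blood cell (0.219), immediate early and heat shock (0.344), regulatory T cell (0.344), epithelial tumour cell (0.346), epithelial-mesenchymal transition (0.421), apoptosis and p53 targets (0.421), unfolded protein response (0.449), NK cell (0.449), fibroblast and matrix (0.555), dendritic cell (0.912) and histone (0.912). The sign of the median, the mean or the test differed for the unfolded protein response, fibroblast, neutrophil and epithelial-mesenchymal transition lists. By fry 0 lists passed (lowest adjusted p = 0.156), and by the exact permutation test of list scores 0 passed (lowest adjusted p = 0.0540). That lowest value came from lists with the smallest p the exact test can give for 5 against 5 libraries (p = 0.00794).

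Across all genes 628 of 11311 passed, 250 higher and 378 lower, and 39 changed at least 2-fold, 28 of them upward. Of 38 named genes tested 26 passed, and 11 of the 26 kept their call under each alternative run for named genes: Pi16, Lbp, Ccl3, Ccl4, Lrrc17, Ogn, Tex101, Gas1, Enpp2, Tgfb3 and Osr2. With the covariates the count was 166 (skeletal muscle) and 201 (adipocyte), the rule of an unadjusted p and a 2-fold change gave 69, and leaving out vehicle replicate 1, 3 or 5 gave 257, 244 or 223. Leaving out anti-PD-1 replicate 1, 2, 4 or 5 gave 285, 317, 344 or 244. It was 2100 with the libraries of these groups alone, 54.2% of them higher, and 2269 with weights per group. With weights per library it was 2392, and 1792 without combination replicates 3 and 5, 54.2% higher. The main fit estimated the spread over all 15 libraries, the wider combination group included. Its median SD was 0.164, against 0.0913 for vehicle and 0.0960 for anti-PD-1. The fit of these groups alone kept the log2 changes and altered only that estimate, so the rise from 628 to 2100 came from it. With its own groups alone, the combination against vehicle gave 3688 genes.

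**Figure D3:**
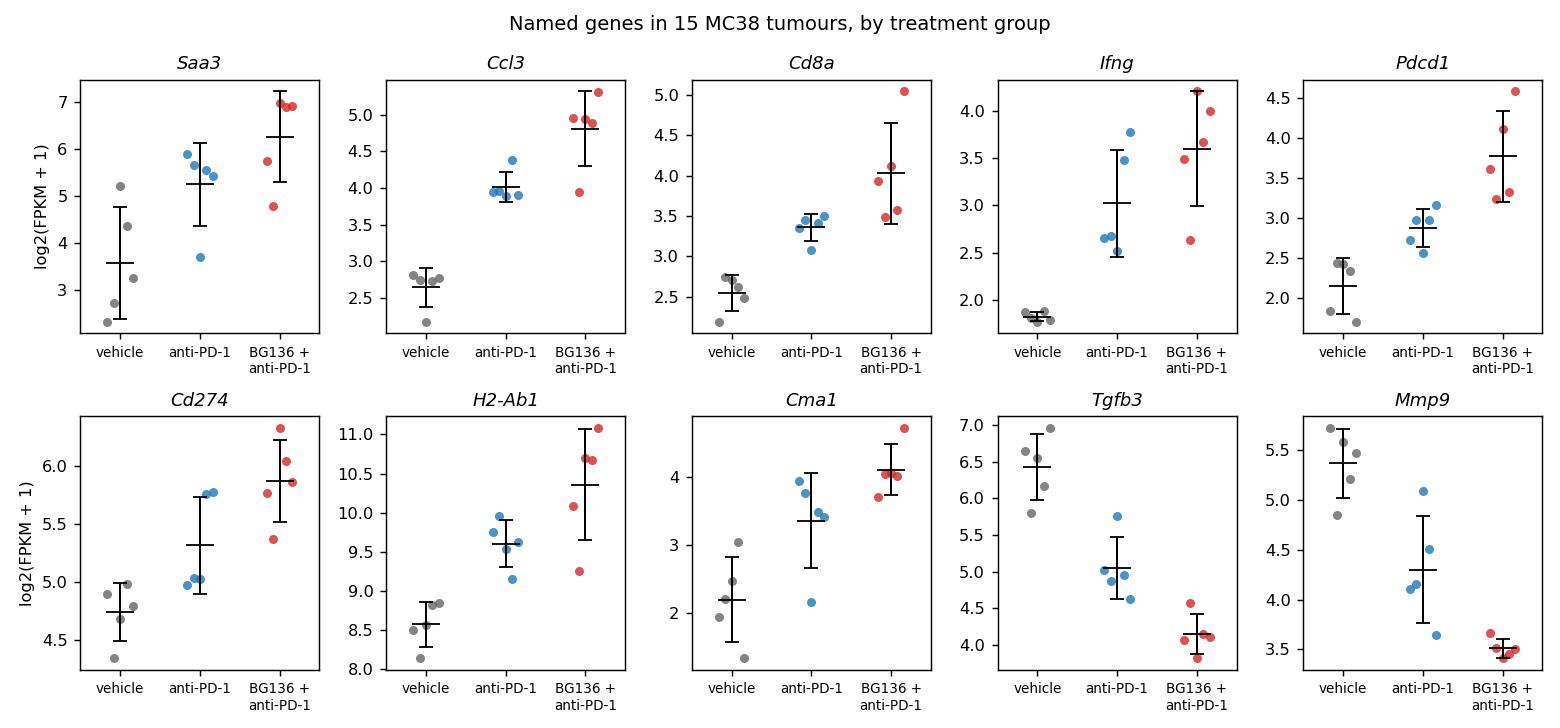
Log2(FPKM + 1) of 10 named genes, with 1 point per library, 5 libraries per group, and the group mean ± SD. Ccl3 and Ifng lie above the vehicle mean and Tgfb3 lies below it in all libraries of both treated groups, and H2-Ab1 averages 386 FPKM with vehicle and 790 with anti-PD-1.

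BG136 plus anti-PD-1 against anti-PD-1 asks what BG136 added to the antibody. Whether the prefixes of the combination libraries name cohorts is unknown, so a cohort difference is not separated here. Few single genes passed: 7 of 11311, all lower with BG136, with 3187 at an unadjusted p under 0.05. Hhipl1 fell from 6.36 ± 0.594 to 4.08 ± 0.630 FPKM (SD, n = 5), a log2 change of -0.54 ± 0.08 (SE, limma adjusted p = 0.0389). Nav1, a neuron navigator protein, fell from 13.2 ± 1.26 to 9.08 ± 1.38, a change of -0.50 ± 0.09 (adjusted p = 0.0452). The others were Unc5a, a netrin receptor, at -0.53 ± 0.09, Plekhh1 at -0.41 ± 0.06, the kinase Pak4 at -0.30 ± 0.05, the endosomal sorting protein Vps37c at -0.28 ± 0.04 and Arl6ip5 at -0.24 ± 0.04. Each of the 7 was lower in all 5 combination libraries than the anti-PD-1 mean, without overlap between the groups. They were picked for passing in these same libraries, which favours such separation, so it adds no support.

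The next genes by p did not pass: Kctd17 at -0.26 ± 0.05, Dhrs13 at -0.32 ± 0.06 and Klrd1, the NK receptor subunit CD94, at 1.12 ± 0.20 (adjusted p = 0.0521 for each). Klrd1 was at 16 ± 6.91 FPKM with BG136 plus anti-PD-1, 6.43 ± 0.798 with anti-PD-1 and 6.05 ± 1.34 with vehicle. Other immune genes had positive differences that did not pass: Ccl4 at 0.73 ± 0.17 and Ccl3 at 0.79 ± 0.20 (adjusted p = 0.0790 for both), and Pdcd1 at 0.90 ± 0.23 (adjusted p = 0.0804). Nkg7 was at 0.92 ± 0.25, Cd28 at 0.62 ± 0.17, Ctla4 at 0.78 ± 0.21 and the lysozyme Lyz2 at 0.86 ± 0.23 (adjusted p = 0.0822 for these 4). Cd3g was at 0.86 ± 0.25, Pycard at 0.50 ± 0.15, Tnf at 0.50 ± 0.16, Tlr4 at 0.25 ± 0.08, Ctss at 0.58 ± 0.19 and C1qb at 0.51 ± 0.17, with adjusted p from 0.0869 to 0.0995. Cd8a at 0.67 ± 0.23, Cd274 at 0.56 ± 0.20, Pecam1 at 0.61 ± 0.22 and H2-Ab1 at 0.75 ± 0.27 did not pass either. Cfp at 0.70 ± 0.26, Nos2 at 0.81 ± 0.32, Egfl7 at 0.41 ± 0.17, Adgre1 at 0.55 ± 0.23, Clec7a at 0.70 ± 0.30, C3ar1 at 0.42 ± 0.19, Ifng at 0.58 ± 0.28 and Gzmb at 0.83 ± 0.42 had adjusted p of up to 0.201.

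As lists, immune genes were higher with BG136 plus anti-PD-1 by camera, with 0 members past over all genes in each list tested. The cytotoxic lymphocyte list was higher by a mean log2 of 0.79 (adjusted p = 3.81e-08, 8 of 12 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation). T cell genes were higher by 0.69 (adjusted p = 7.68e-08, 11 of 11 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation). The beta-glucan list was higher by 0.40 (adjusted p = 7.68e-08, 11 of 15 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation). The checkpoint list was higher by 0.56 (adjusted p = 7.68e-08, 10 of 11 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation). Macrophage and monocyte markers were higher by 0.54 (adjusted p = 1.49e-07, 9 of 13 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation). MHC class II genes were higher by 0.58 (adjusted p = 1.83e-06, 8 of 10 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation). The proliferation list was lower, with a mean of -0.16 (adjusted p = 0.00250, 2 of 18 adjusted over the list alone, adjusted p = 0.497 with an estimated correlation). Much of these differences lay in combination replicates 3 and 5. Without both libraries the means were 0.389 for the cytotoxic lymphocyte list, 0.293 for T cell, 0.138 for beta-glucan, 0.297 for checkpoint, 0.122 for macrophage and monocyte and 0.228 for MHC class II. These 6 lists still passed camera at the preset correlation (highest adjusted p = 0.00191), and proliferation, at -0.0461, did not (adjusted p = 0.603). The smallest adjusted p without both libraries was that of hypoxia and glycolysis, which was higher by 0.314 (adjusted p = 2.64e-10) in place of 0.0337 (adjusted p = 0.215). Type I interferon passed as well, at -0.330 (adjusted p = 3.30e-04). Without combination replicate 5 alone the means were 0.437 for T cell, 0.346 for macrophage and monocyte and -0.0973 for proliferation.

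The remaining lists past camera were all higher, with adjusted p from 0.309 to 0.666 with an estimated correlation. They were endothelium (adjusted p = 1.22e-04, 0 adjusted over the list alone), complement (1.22e-04, 0), pro-inflammatory macrophage (4.06e-04, 0), chemokine (0.00107, 3 higher and 1 lower), immediate early and heat shock (0.00200, 3), NK cell (0.00630, 2), mast cell and eosinophil (0.0107, 0), alternatively activated macrophage (0.0107, 1), epithelial tumour cell (0.0140, 0), regulatory T cell (0.0191, 0), interferon gamma response (0.0263, 0), red blood cell (0.0299, 0), matrix metalloproteinase and invasion (0.0309, 0) and neutrophil (0.0411, 1 lower). Without combination replicates 3 and 5 the calls of 8 of these lists ended: complement (a mean of 0.0909 in place of 0.439, adjusted p = 0.152), endothelium (0.0682 in place of 0.339, adjusted p = 0.199), pro-inflammatory macrophage (0.189 in place of 0.467, adjusted p = 0.0571), regulatory T cell (0.0670 in place of 0.341, adjusted p = 0.428), alternatively activated macrophage (adjusted p = 0.155), matrix metalloproteinase (0.152), red blood cell (0.0620) and neutrophil (0.215). Chemokine (0.0350), immediate early and heat shock (8.77e-04), NK cell (0.00324), mast cell (0.0409) and interferon gamma (0.0350) still passed, and epithelial tumour cell was not tested in that fit. Without combination replicate 5 alone the means were 0.260 for complement and 0.180 for endothelium. Leaving out anti-PD-1 replicate 3 alone ended the calls of alternatively activated macrophage, epithelial tumour cell, interferon gamma, mast cell, matrix metalloproteinase, neutrophil, red blood cell and regulatory T cell (adjusted p from 0.0506 to 0.0932), and brought chemokine to a mean of 0.232. The alternatively activated macrophage mean was 0.462 without anti-PD-1 replicate 2 and 0.154 without anti-PD-1 replicate 5. Interferon gamma lay between 0.0316 without anti-PD-1 replicate 1 and 0.197 without anti-PD-1 replicate 5, and its call also ended without anti-PD-1 replicate 1 or 2 or combination replicate 1, 3 or 4. Other single libraries whose loss ended calls were combination replicates 3, 4 and 5 for epithelial tumour cell, combination replicates 2 and 5 and anti-PD-1 replicate 5 for matrix metalloproteinase, combination replicates 4 and 5 and anti-PD-1 replicate 5 for red blood cell, and combination replicates 2 to 5 and anti-PD-1 replicates 4 and 5 for neutrophil. Not past were oxidative phosphorylation (adjusted p = 0.0751), type I interferon response (0.0858), MHC class I presentation (0.134), adipocyte (0.134), dendritic cell (0.175), fibroblast and matrix (0.195), hypoxia and glycolysis (0.215), apoptosis and p53 targets (0.336), histone (0.336), skeletal muscle (0.623), unfolded protein response (0.757), ribosomal protein (0.757) and epithelial-mesenchymal transition (0.885). Median, mean and test differed in sign for the hypoxia, apoptosis, skeletal muscle and epithelial-mesenchymal transition lists. By fry, which tests each list alone, 0 lists passed (lowest adjusted p = 0.0744), and by the exact permutation test of list scores 0 passed (lowest adjusted p = 0.216).

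The count of 7 rested on the set of libraries: it was 2222 without combination replicate 2, 4 without combination replicate 1, and 0 without any other single library of these groups. It was also 0 without combination replicates 3 and 5 together, with these groups alone, with weights per group, under both other scalings and with the adipocyte covariate. It was 24 at a minimum of 5 FPKM, 18 with weights per library and 18 by the rule of an unadjusted p and a 2-fold change. In 200 simulations without an effect that kept the spreads of the groups, at least 7 genes passed in 21.5% with genes drawn independently and in 8.5% with the residuals of each library kept together. Chance is therefore not excluded for the 7 calls. The list count was 13 without anti-PD-1 replicate 3.

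Both treated groups were compared with the same 5 vehicle libraries, so their changes share error. Across genes, which are not independent replicates, the log2 changes of both comparisons correlated at 0.875, against a mean of 0.521 and a highest value of 0.937 in 100 simulations without an effect. Their covariance was 0.0845 against 0.0102 simulated, a difference of 0.0743. Genes higher in both comparisons numbered 214 (simulated mean 0.01), genes lower in both 372 (simulated mean 0.02), and 0 went in opposite directions. These simulations drew the residuals of libraries from all groups together, with replacement, so the spread of each group was not kept. The simulated values are therefore only a rough guide to what the shared vehicle libraries give without an effect. With the vehicle libraries divided between the comparisons in 20 arrangements, the correlation lay between 0.678 and 0.853, with 3 to 174 genes higher and 0 to 219 lower in both. Among genes past the threshold with anti-PD-1 alone, 93.3% passed in the same direction with the combination.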

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

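The tests of explanations in this part, the counts of other splits included, were chosen only after the results they address had been seen, except that median-ratio and quantile scaling and the skeletal muscle covariate were alternatives fixed before, as was the criterion for a value far from the rest of its group. That criterion (the gap to the nearest library over the group's range, Dixon's 95% value for 5 libraries) picks about 1 in 20 groups by chance. It picked 12 of 225 groups of gene values (5.33%), 3 of 108 of list scores (2.78%) and 2 of 27 of library measures (7.41%). Combination replicates 4 and 5 had 4 each, the most of any library.

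In combination replicate 5 the T cell genes Cd8a (32.0 FPKM, the others 10.2 to 16.3) and Cd3g (50.9, the others 14.6 to 24.6), the mast cell chymase Cma1 (25.5, the others 12.1 to 15.7) and Gpx3 (189, the others 50.2 to 84.9) stood above the rest. In combination replicate 4 Gas1 was high (24.8 FPKM, the others 13.1 to 15.4), the skeletal muscle score low (0.173, the others 3.16 to 3.74), the FPKM sum high (424899, the others 385616 to 393318) and the Spearman correlation with gene length, across genes, far below the others (-0.420, the others -0.0189 to 0.0826). With vehicle, Nppb was high in replicate 2 (2.93 FPKM, the others 0.464 to 0.831), Gzmb low in replicate 2 (18.4, the others 30.5 to 35.2), Ccl3 low in replicate 3 (3.51, the others 5.64 to 6.04), Clec3b high in replicate 4 (7.85, the others 1.37 to 1.96) and Ly6g above 0 in replicate 5 (0.0634). With anti-PD-1, Ccl3 was high in replicate 4 (19.8, the others 13.9 to 14.6), Tgfb3 high in replicate 3 (53.4, the others 23.8 to 31.7), the regulatory T cell score low in replicate 3 (0.827, the others 1.19 to 1.30) and the dendritic cell score high in replicate 2 (2.03, the others 1.83 to 1.87).

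The T cell, cytotoxic lymphocyte, macrophage and MHC class II scores were higher with BG136 plus anti-PD-1 than with vehicle. A lower share of tumour cells alone would raise the markers of every other cell type alike, but the cytotoxic score rose by 0.689 more than the endothelial one (log2, exact permutation p = 0.00794, the smallest possible; group SDs 0.116 and 0.273). This speaks for the cytotoxic score only. The macrophage score rose by 0.871 and the endothelial one by 0.635 (combination SDs 0.597 and 0.449), so a lower tumour share stays open there. T cell and MHC class II scores were not compared in this way. Admixed fat or muscle as the whole source is argued against by the differences left with those scores as covariates, of which the smallest relative to its error was 0.712 (SE 0.251, macrophage with adipocyte). Combination replicates 3 and 5 alone do not carry the pattern: without them the smallest difference was 0.455 (exact p = 0.0179, the smallest possible). More immune cells in the tumour, or more expression per cell, may account for the rise; bulk values do not separate these.

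The type I interferon list was lower in both treated groups, but with anti-PD-1 the difference lay mostly in replicates 1 and 2 (scores 4.75 and 4.79). Replicates 3 and 4 (5.46 and 5.42) lay within the vehicle range of 5.36 to 5.63 and replicate 5 (5.25) just below it. Without replicates 1 and 2, picked as the lowest, the difference was -0.128 in place of -0.371, less than the vehicle SD of 0.137. Dilution by infiltrating cells was first looked at through the correlation of this score with the macrophage score within groups, over 15 libraries, which decided nothing (Spearman rho 0.282, permutation p = 0.363; Pearson r 0.393, permutation p = 0.209, and 0.101 without combination replicates 3 and 5), and was then replaced by a comparison with the proliferation score. Dilution would lower both alike, but type I interferon minus proliferation was -0.512 with the combination (exact p = 0.0317; highest group SD 0.411), with the reserve that infiltrating cells divide too. With anti-PD-1 it was -0.469 (exact p = 0.0317), but -0.253 without replicates 1 and 2, within that SD, so dilution stays open there. Scaling between libraries as the cause is argued against by the means left under median-ratio scaling, -0.514 for the combination and -0.37 for anti-PD-1, beside -0.58 and -0.37 as deposited. Lower interferon signalling with the combination may remain as a hypothesis, and for anti-PD-1 the 2 low libraries alone may account for the difference.

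Few genes passed between BG136 plus anti-PD-1 and anti-PD-1. The median SD of log2 values was 1.71 times as large in the combination group (exact p = 0.00794), which may limit the calls. In the simulated data with these spreads, 57 of 67 genes changed 1.5-fold and 64 of 67 changed 2-fold were still recovered in this comparison. Those changes were put only in genes with a mean log2(FPKM + 1) of at least 2, and genes were drawn independently. Recovery where whole libraries shift together, or in lower genes, was therefore not measured. Smaller changes were not simulated. The length trend of combination replicate 4 was taken out with the library kept, which brought its Spearman correlation with gene length from -0.420 to -0.0123. The genes at an unadjusted p under 0.05 then numbered 3272, against 3187, and the ratio of median SDs was 1.65. This argues against the trend as the cause of the low count, while the 7 calls ended (0 genes passed). The count also hung on combination replicate 2, without which 2222 genes passed. Its T cell and cytotoxic scores (2.49 and 3.45) lay within the anti-PD-1 ranges of 2.09 to 2.58 and 3.20 to 3.74. That library was singled out after the counts were seen, and why it lay there was not tested. An effect of BG136 beside anti-PD-1, and its size, stay open. The comparison was tested but did not settle this: camera at the preset correlation passed 21 lists, while fry and the exact permutation test of list scores passed 0.

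Among 100 splits of the 10 libraries of each comparison, chance could be excluded for the gene counts against vehicle: 1 split gave as many as 4578 for the combination (highest other 2165) and 1 as many as 628 for anti-PD-1 (highest other 0). Between the treated groups 4 splits gave as many as 7 (highest other 101), but chance was not excluded by the simulations added for it. In 200 simulations without an effect that kept the spreads of the groups, 21.5% gave as many as 7 with genes drawn independently (highest 18) and 8.5% with the residuals of each library kept together (highest 2086). The split with 101 calls, several times the real count, may reflect a structure of the samples beyond the groups or the unequal spread, and these were not separated. The same simulations gave at most 1857 for the combination against vehicle and 18 for anti-PD-1 against vehicle. For the list counts, 2 splits, the real one included, gave as many as 23 for the combination against vehicle (highest other 23). A relabelled split thus reached the same count, so chance is less likely there but not excluded. Nor could chance be excluded for anti-PD-1 against vehicle (16 splits gave as many as 17, highest other 22) or for the combination against anti-PD-1 (14 splits gave as many as 21, highest other 24). The other splits gave a median of 14, 10 and 13 lists in these comparisons, so camera at the preset correlation calls many lists under relabelled groups too.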

How the results depend on the processing

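Alternatives chosen after seeing the data were the adipocyte covariate, leaving out combination replicates 3 and 5 together, the fits with the compared groups alone or with weights per group, and the exact permutation of list scores. The others were fixed before. Against vehicle, all 35 named genes past the threshold stayed past it under each alternative run for them. The combination's count stayed within 1.5 times of 4578 except with the adipocyte covariate (2519) and with an unadjusted p and a 2-fold rule (413). Leaving out single libraries gave 3728 to 5201. Under median-ratio scaling the split turned, with 2272 higher and 1809 lower. For anti-PD-1 against vehicle, 628 became 2392 with weights per library, 2269 with weights per group, 2100 with the compared groups alone and 1792 without combination replicates 3 and 5. It became 347 with the replicate block, 166 and 201 with the muscle and adipocyte covariates, 69 with the 2-fold rule, and 223 to 646 without single libraries. For the combination against anti-PD-1, 7 became 24 at a minimum of 5 FPKM, 18 with weights per library, 18 with the 2-fold rule, and 0 under median-ratio scaling, quantile scaling, the replicate block, the adipocyte covariate, the compared groups alone, weights per group, and without combination replicates 3 and 5. Without single libraries it was 0 to 2222. List counts of 23, 17 and 21 became 0, 0 and 0 with an estimated correlation. Fry and the exact permutation gave 0 for anti-PD-1 against vehicle and for the combination against anti-PD-1. For the combination against anti-PD-1 single libraries moved 21 to between 13 and 23. The replicate numbers did not pair tumours (own number best in 1 of 15, r -0.388 to 0.293). Of the lists past camera 16 of 23, 13 of 17 and 13 of 21 (in the order of the comparisons above) kept their call without each single library, and 14, 11 and 9 under the other settings of camera with the preset correlation. Of the named genes past the threshold 11 of 26 with anti-PD-1 alone and 0 of 7 between the treated groups kept theirs. With the compared groups alone the log2 changes stayed the same and only the estimate of spread differed, so that estimate moved those counts. The cause of the other changes was not tested.

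Changes of sign were of lists, or of Gzmb and Clec7a, past the threshold in neither fit in 62 cases, and the cause was not tested. The values are mean log2 changes. For the combination against vehicle, under median-ratio scaling they were epithelial-mesenchymal transition 0.0325, oxidative phosphorylation 0.00371 and unfolded protein response 0.0407. Under quantile scaling they were histone -0.0249. With weights per library they were proliferation 0.0281 and unfolded protein response 0.0324. With the adipocyte covariate they were unfolded protein response 0.0339. Without combination replicates 3 and 5 they were hypoxia 0.154, oxidative phosphorylation 0.0141, proliferation 0.0526, ribosomal protein 0.0288 and unfolded protein response 0.0714. For anti-PD-1 against vehicle, under quantile scaling they were histone -0.0531 and unfolded protein response -0.000405. With the muscle covariate they were histone -0.0170. With the adipocyte covariate they were dendritic cell -0.00862, fibroblast -0.0346 and neutrophil -0.137. For the combination against anti-PD-1, with a pseudocount of 0.1 they were epithelial-mesenchymal transition -0.00175. Under median-ratio scaling they were ribosomal protein 0.00569 and unfolded protein response 0.0118. With weights per library they were epithelial tumour cell -0.0146, epithelial-mesenchymal transition -0.0720, fibroblast -0.0451, histone -0.0188 and skeletal muscle 0.295. Without combination replicates 3 and 5 they were epithelial-mesenchymal transition -0.117, fibroblast -0.0434, ribosomal protein 0.0868 and unfolded protein response 0.0455. In the last comparison the epithelial tumour cell list had passed as reported (adjusted p = 0.0140) and no longer did with weights per library, and ribosomal protein was past the threshold without combination replicates 3 and 5 (adjusted p = 5.44e-05).

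Leaving out single libraries turned the sign within these ranges. For the combination against vehicle they were epithelial-mesenchymal transition -0.0822 to 0.00507, hypoxia -0.215 to 0.0424, proliferation -0.114 to 0.00135, histone -0.0324 to 0.0885 and unfolded protein response -0.0611 to 0.0374. For anti-PD-1 against vehicle they were Clec7a -0.291 to 0.101, Gzmb -0.0934 to 0.414, fibroblast -0.0261 to 0.176, neutrophil -0.0553 to 0.243 and histone -0.0494 to 0.104. For the combination against anti-PD-1 they were epithelial-mesenchymal transition -0.0507 to 0.0366, hypoxia -0.0546 to 0.202, histone -0.0864 to 0.0693, ribosomal protein -0.122 to 0.0145, skeletal muscle -0.449 to 0.458 and unfolded protein response -0.0870 to 0.0114. Skeletal muscle was higher between the treated groups, and passed, without combination replicate 4 (adjusted p = 0.0253). The absolute depth is unknown, so its limit on genes near 1 FPKM was not measured.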

Other observations

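Sterol synthesis genes and sterol efflux genes moved in opposite directions with BG136 plus anti-PD-1. These 2 lists were assembled after the values had been seen, so no test of them is given. Of 23 sterol synthesis genes tested, 17 fell and 0 rose against vehicle, and the mean over the list differed by -0.64 on the log2 scale, lower in 5 of 5 libraries. Cyp51, the lanosterol demethylase, was at 22.6 ± 11.3 FPKM with the combination (SD, n = 5), 38.9 ± 5.11 with anti-PD-1 and 47.6 ± 9.22 with vehicle. Hmgcs1, at the entry of the pathway, changed by -1.01 ± 0.26 (SE) against vehicle. Between anti-PD-1 and vehicle the list differed by -0.06, and between the combination and anti-PD-1 by -0.58, with 0 members past over all genes. Of 11 efflux and lipoprotein genes 10 rose and 1 fell with the combination against vehicle, with a mean difference of 1.27. The cholesterol transporters Abca1 and Abcg1 changed by 1.35 ± 0.29 and 1.55 ± 0.30, Apoe by 1.18 ± 0.30, and the sterol-sensing receptor Nr1h3 (LXR alpha) by 1.39 ± 0.23, while Lpcat3 changed by -0.35 ± 0.08. The combination libraries varied widely, with Abca1 at 25.8 ± 15.9 FPKM (SD, n = 5) and Abcg1 at 18.6 ± 12.1. Several of the efflux genes are expressed by macrophages or fat cells, and the macrophage and adipocyte lists were higher in the same comparison, by means of 0.87 and 1.38. A change within cells was not separated from a change in cell content. With anti-PD-1 alone the efflux list was higher by 0.69 with 0 members past, and between the treated groups it differed by 0.58. Signs were the same under median-ratio and quantile scaling.

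Fibroblast and matrix genes went both ways with the combination against vehicle, 6 rising and 4 falling of 14, and are named here after their values were seen. The collagen I chains Col1a1 and Col1a2 changed by 1.27 ± 0.32 and 1.76 ± 0.37 and the proteoglycan Lum by 1.47 ± 0.33. In contrast the collagens Col3a1, Col5a1 and Col6a1 changed by -0.82 ± 0.15, -0.98 ± 0.11 and -0.997 ± 0.16, and the growth factor receptor Pdgfra by -1.20 ± 0.12. In the epithelial-mesenchymal transition list the transcription factors Snai1, Twist1 and Zeb1 changed by -1.13 ± 0.11, -0.49 ± 0.11 and -0.70 ± 0.11 and fibronectin (Fn1) by -1.16 ± 0.16, while Zeb2 changed by 0.47 ± 0.14 and Mmp2 by 0.95 ± 0.27.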
